A study of Mus musculus with 6 samples.

How the data were processed

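RNA was measured in 6 libraries of mouse trophoblast stem cells, 3 grown in the medium labelled FBS and 3 in the medium labelled KSR. Per the labels' protocols, total RNA was extracted with TRIzol and strand-specific SureSelect RNA libraries were made, and per the file headers the reads were paired. The authors deposited RPKM values (reads scaled by transcript length and by the mapped reads of the library), 1 column per library and not pooled, per the file headers. The genome build was mm9, per the submitters' processing notes. The aligner, the counting method, the gene annotation and any filter are not given in the sources used here, so that the treatment of reads shared by similar genes, and whether counting used the strand, is unknown. RPKM divides each library by its own total, so that a change in a few abundant transcripts moves every other value, and it divides by a model length that depends on the annotation.

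Each table has 30208 rows, of which 133 have no symbol and took 0.301% to 0.367% of the summed RPKM per library. Those 133 were left out of the tests. The other rows hold 23273 symbols, 4118 of them with several rows (up to 22), and 24 symbols had been turned into dates by a spreadsheet. The row with the highest mean stood for a repeated symbol. In all 6 libraries 6309 symbols are listed at 0, among them the abundant noncoding transcripts Malat1 and Neat1 and the imprinted gene H19, so that 0 is reported only as listed. Egr1, Srf, Hand1, Ascl2, Tpbpa, Gcm1, Syna, Synb, Prl3d1, Hmgcs1 and Rn7sk, members of the fixed lists, were not analysed here.

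Depth was recovered from the values. In a row, RPKM values are whole multiples of the worth of 1 read, and with 1 relative depth per library whole reads within 0.01 were found for 100% of 22847 rows above 0. Of these rows 17700 were above 0 in all 6 libraries, and a row above 0 in 1 library gives whole reads trivially. Up to a lowest count of 88, 0% of 2000 rows mixed from different genes gave whole reads. The bound of 88 is the median of the real rows, so that 50.2% of them lay within it by construction. The rows held 7082043, 7606972 and 5769647 reads in FBS replicates 1 to 3 and 6414631, 7208467 and 6170609 in KSR replicates 1 to 3 (reads or read pairs, which the sources do not say), or 83.2% to 84.9% of the library total behind the RPKM scale. Replicates of a medium differed by more than sampling noise (chi-square per degree of freedom of 3.29 to 8.45), and all were kept as separate samples.

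Libraries were grouped by the growth label. Genes with a mean of at least 1 RPKM over the 6 libraries were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are therefore on the log2(RPKM + 1) scale, which understates the change of low genes. A change of at least 2-fold was an absolute log2 fold change of at least 1. The 26 gene lists, the tests, the rule for named genes and the first set of alternatives were fixed before the data were examined. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with an estimated correlation. Members were matched by symbol or synonym (RefSeq table of assembly GRCm38.p6) and counted by the gene test. That assembly differs from mm9, so no coordinates are given, and it served only for names, chromosomes and gene order.

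Genes were named by rule: the 12 largest rises and 12 largest falls past the test whose KSR libraries all lay beyond the FBS libraries, leaving out predicted genes and small RNAs; Cdx2, Eomes, Elf5, Esrrb, Sox2 and Tfap2c; and up to 4 members of each list with the largest change past the test, or the 2 most abundant where fewer than 2 passed. Other members named, such as those that went against their list, were chosen after their values were seen.

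Alternatives were pseudocounts of 0.1 and 0.5, minimum means of 0.1 and 5 RPKM or none, rescaling by the median of ratios, by a fixed sum or by quantiles, limma without the trend or with sample weights, a block by summed passage number, the mean of repeated rows, and each library left out in turn. Chosen after seeing the data were limma-voom on the recovered reads, the sum of repeated rows, centring of each chromosome's genes (98.1% of tested genes had a chromosome) and a correction for GC content and length (99.7% had a GC content, from the longest GENCODE transcript).

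The tests were run on simulated reads for 10949 genes with the real means and depths and a dispersion of 0.02, with 200 genes changed. Of these, 33.3% were called at 1.5-fold, 94% at 2-fold and 100% at 4-fold, and 6.2% of all calls were false. Without any change 1 gene was called. These rates hold for the simulated setting only, since 42% of the tested genes changed in the data and the dispersion was not estimated from them. A list moved in the simulation was called and no other was. The simulated genes varied independently of each other, so that this does not show how camera behaves with correlated genes. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and numba 0.67.0, and plots were drawn with matplotlib 3.10.9.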

Results

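Transcript levels were measured by RNA sequencing in mouse trophoblast stem cells of the ICR strain, the self-renewing cells of the early placental lineage. The cells were kept undifferentiated for 4 days in either of 2 media. The conventional medium, labelled FBS, held the growth factor FGF4, its cofactor heparin and conditioned medium. The other, labelled KSR, was used on fibronectin-coated dishes with combinations of FGF4 at 25 ng/ml, heparin, activin A at 10 ng/ml, the retinoic acid receptor inverse agonist BMS493 at 1 µM and the ROCK inhibitor Y-27632 at 10 µM. Each medium had 3 libraries, with the passage labels 44, 45 and 46 for FBS replicates 1 to 3 and 38+7, 38+6 and 38+8 for KSR replicates 1 to 3. The labels do not say whether the replicates were separate cultures beyond these passages, so that p-values measure the spread between these libraries, which may be technical. Every KSR library also had another passage history than the FBS libraries, so that an effect of the medium cannot be told apart from it. The deposited values gave 5769647 to 7606972 reads per library in the gene rows. The first principal component held 75.5% of the variance and separated the media, with scores from -30.8 to -27.2 in FBS and from 28.1 to 31.1 in KSR.

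The first question was how the transcriptome differed between the media. Emp1, a tetraspan membrane protein, rose in KSR by 4.77 ± 0.15 on the log2 scale (SE), from 1.90 ± 0.597 to 77.3 ± 8.83 RPKM (SD, n = 3 per medium). Igf2bp2, an RNA-binding protein of the IGF2 mRNA-binding family, fell by 4.79 ± 0.10, from 50.4 ± 1.22 to 0.867 ± 0.163 RPKM. Other large rises were those of the collagen chaperone Fkbp10 (3.63 ± 0.17), the gap junction protein Gja1 (3.55 ± 0.16), the type I collagen chain Col1a1 (3.50 ± 0.24), the myelin protein Pmp22 (3.43 ± 0.14) and the insulin-like growth factor binding protein Igfbp4 (2.99 ± 0.14). Crispld2, Sh3bgrl, the complement component C2, the prostaglandin E synthase Ptges, the growth factor receptor Pdgfrb and Capn6 rose by 2.66 to 3.18. Among the largest falls were those of the chromatin protein Hmga2 (-2.74 ± 0.13), the tight junction protein Cldn7 (-2.81 ± 0.22), the homeobox gene Rhox4g (-2.91 ± 0.28), Trp53i11 (-2.83 ± 0.18), Gtsf1l (-2.67 ± 0.19) and the potassium channel Kcnc4 (-2.63 ± 0.18). The other 5 of the 12 largest falls, Prl7a1, Prl2c5, Prl2c3, Prl2c2 and Ctsj, belong to placental prolactin and cathepsin families and are described with the giant cell genes. Of 10949 genes tested, 4603 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 2438 of them higher and 2165 lower in KSR. Of these, 385 were at least 2-fold higher and 417 at least 2-fold lower, 802 in all. The 3 KSR libraries all lay beyond the 3 FBS libraries for 54.8% of the tested genes, where chance gives 10%. The count of 802 was 439 when only genes with a mean of at least 5 RPKM were tested. Genes were not shifted alike along the genome, since the median log2 fold change was 0.45 for chromosome 8, 0.35 for chromosome 18 and -0.28 for chromosome 6, against 0.01 for all genes (chromosomes by symbol from RefSeq, GRCm38.p6).

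**Figure D1:**
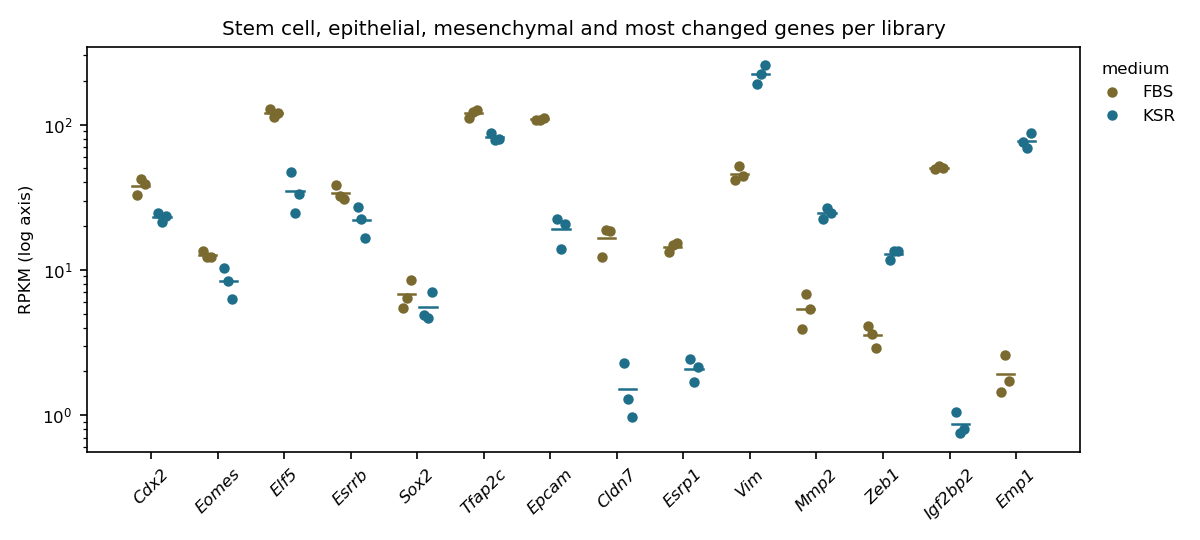
RPKM (log axis) of 14 genes in each of the 3 FBS and 3 KSR libraries, with each point a library and each bar a group mean. The 3 Elf5 values average 120.6 RPKM in FBS and 35.0 in KSR, Vim averages 45.9 and 223.6, and the groups overlap for Sox2.

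The next question was whether the stem cell genes were held in KSR. Of the 6 core transcription factors, Elf5 fell by 1.80 ± 0.19 on the log2 scale, from 120.6 ± 7.51 to 35.0 ± 11.3 RPKM. Cdx2 fell by 0.68 ± 0.10 (37.9 to 23.1 RPKM), Eomes by 0.57 ± 0.15 (12.7 to 8.35) and Tfap2c by 0.54 ± 0.08 (119.7 to 82.0). Sox2 did not pass the test, at 6.80 ± 1.55 and 5.53 ± 1.27 RPKM. The nuclear receptor Esrrb has 2 rows, of which the more abundant fell by 0.62 ± 0.17 (33.9 to 22.0 RPKM) and the other rose by 2.02 ± 0.21 (5.96 to 27.7). With both rows of Esrrb summed, its log2 fold change was 0.30. Over the 17 trophoblast stem cell genes, 12 fell, 1 rose and 4 did not pass, with the same counts when adjusted over the list alone. Without KSR replicate 2 or 3 the count that fell was 10, and with the rows of a symbol summed it was 11. The falls included the helix-loop-helix factor Id2 (-1.26 ± 0.08), the RNA-binding protein Lin28a (-1.18 ± 0.12) and the FGF receptor Fgfr2 (-1.04 ± 0.16). The list lay lower than other genes in KSR (median -0.62, camera adjusted p = 0.000334, but adjusted p = 0.594 with an estimated correlation). The rise was that of Bmp4 (0.95 ± 0.25), a signal of the early embryo, which did not pass without FBS replicate 3.

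Epithelial genes were lower and mesenchymal genes higher in KSR. Of 13 epithelial genes tested, 10 fell, 1 rose and 2 did not pass, alike when adjusted over the list alone. The adhesion protein Epcam fell by 2.49 ± 0.15 (108.8 to 18.9 RPKM), the splicing factor Esrp1 by 2.33 ± 0.12 (14.4 to 2.09) and the tight junction protein Cldn3 by 1.68 ± 0.15 (71.8 to 21.9). E-cadherin (Cdh1) fell by 0.96 ± 0.16, while Tjp1, a tight junction scaffold, rose by 0.55 ± 0.09. The epithelial median was -1.17 (camera adjusted p = 0.00017, adjusted p = 0.594 with an estimated correlation). Of 6 mesenchymal genes, 5 rose and 1 fell, alike when adjusted over the list alone. The intermediate filament Vim rose by 2.26 ± 0.12 (45.9 to 223.6 RPKM), the gelatinase Mmp2 by 2.02 ± 0.16, and the repressors Zeb1 by 1.62 ± 0.13 and Snai1 by 1.17 ± 0.24. N-cadherin (Cdh2) fell by 0.99 ± 0.18, although without FBS replicate 1 or 2 its mean was too low to be tested. The mesenchymal median was 1.39 (camera adjusted p = 0.0101, adjusted p = 0.594 with an estimated correlation), but 0.86 with a mean of at least 0.1 RPKM (adjusted p = 0.043) and 0.63 over all 11 members without a filter (adjusted p = 0.0395). Of 4 fibroblast markers tested, Col1a1 and Pdgfrb (2.72 ± 0.16) rose and Col6a2 fell (-1.29 ± 0.16), alike when adjusted over the list alone, and the list was not called (adjusted p = 0.215) except without FBS replicate 3, where Col6a2 was too low to be tested, and with a mean of at least 5 RPKM. The other fibroblast collagens Col1a2 and Col3a1 averaged 0.00755 and 0.0726 RPKM in KSR. Of 18 extracellular matrix and integrin genes, 8 rose and 3 fell (9 and 4 adjusted over the list alone), with the largest rise in fibronectin (Fn1, 1.31 ± 0.35), which did not pass without FBS replicate 3, followed by the integrin chains Itgb1 (1.07 ± 0.10) and Itga3 (1.01 ± 0.13) and the basement membrane collagen Col4a2 (1.03 ± 0.09). This list was not called (adjusted p = 0.0941) except without FBS replicate 1 and with a mean of at least 0.1 RPKM or no filter.

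**Figure D2:**
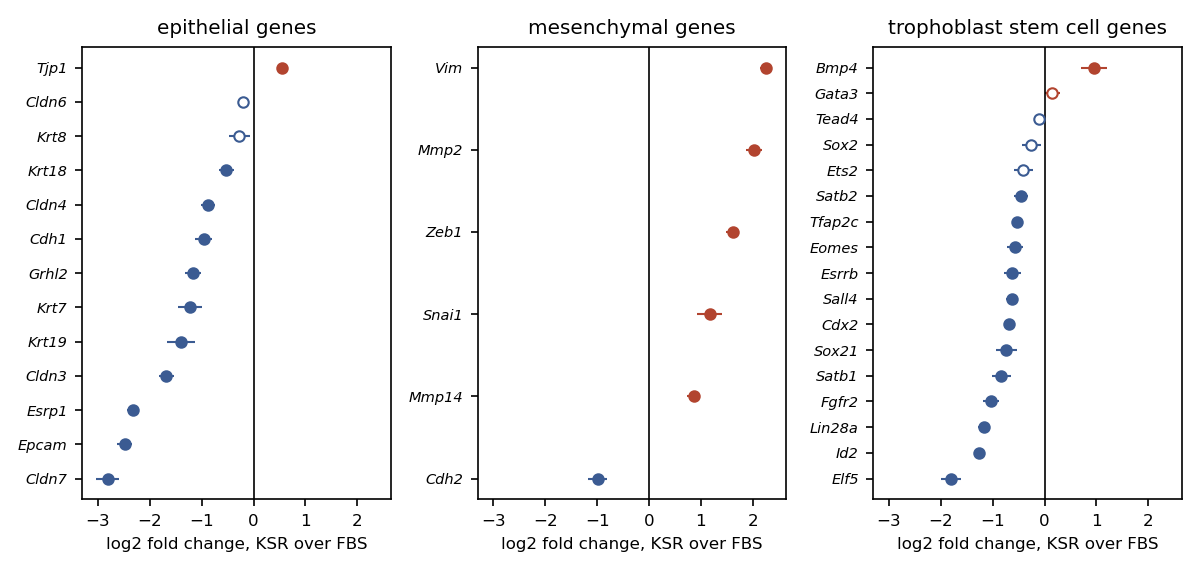
Log2 fold change of KSR over FBS for each tested member of the epithelial, mesenchymal and trophoblast stem cell lists, with bars of 1 standard error (3 libraries per medium) and filled points for genes past the test. Of the epithelial genes 10 lie below 0 and pass, and of the mesenchymal genes 5 lie above 0 and pass.

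Since the KSR medium was used with combinations of FGF4, activin A, a retinoic acid receptor inverse agonist and a ROCK inhibitor, targets of these pathways were examined. The FBS medium held FGF4 too, so changes of FGF and ERK genes cannot be credited to its presence in KSR. The labels do not say which KSR library had which supplements, so the 3 may differ in treatment. Of 16 FGF and ERK response genes, 11 rose, 1 fell and 4 did not pass (11 and 2 adjusted over the list alone). The cyclin Ccnd1 rose by 2.44 ± 0.14 (1.17 to 10.8 RPKM), the ETS factor Etv4 by 1.94 ± 0.31, Phlda1 by 1.68 ± 0.24 and the feedback inhibitor Spry4 by 1.32 ± 0.16. Their median was 1.12 (camera adjusted p = 0.00146, adjusted p = 0.594 with an estimated correlation), and 0.92 with 10 rising after centring by chromosome. Myc, the member that fell (-0.42 ± 0.12), did not pass without FBS replicate 1 or 2 or KSR replicate 2 or 3, and without KSR replicate 1 Fosl1 fell too, making 2. Fos did not pass, with 121 RPKM in KSR replicate 1 and 10.3 and 10.7 in the other KSR libraries. Of 9 activin and Nodal response genes, 5 rose and 4 did not pass, alike when adjusted over the list alone. They included Pmepa1 (0.78 ± 0.14), Tgif1 (0.74 ± 0.12), the chromosome 18 gene Bambi (0.73 ± 0.15), which did not pass after centring by chromosome, and the Nodal antagonist Lefty2 (1.85 ± 0.49), which did not pass without KSR replicate 3. The activin list lay at the threshold (median 0.52, camera adjusted p = 0.0492, adjusted p = 0.594 with an estimated correlation) and was not called without FBS replicate 3, KSR replicate 1 or KSR replicate 3, where its adjusted p was 0.0717, 0.08 and 0.0597. Nor was it called with a pseudocount of 0.1 or 0.5, a mean of at least 5 RPKM, a fixed sum of RPKM, sample weights, the mean or sum of repeated rows, voom or centring by chromosome. Of 10 retinoic acid response genes, 4 rose and 3 fell, alike when adjusted over the list alone, with the retinal reductase Dhrs3 (1.71 ± 0.33), Cdx1 (1.07 ± 0.15) and Crabp2 (1.06 ± 0.23) higher. These genes were low, from 1.00 to 6.07 RPKM for Dhrs3, 0.791 to 2.77 for Cdx1 and 0.622 to 2.3 for Crabp2. With a mean of at least 5 RPKM, 1 list member rose and 2 fell, with a median of -0.48. The transglutaminase Tgm2 was lower (-1.85 ± 0.51, -1.23 without FBS replicate 1, which had 130.8 RPKM against 27.5 and 44.7), but not past the test without KSR replicate 2 or 3, where only 1 list member fell. The retinoic acid list was not called (adjusted p = 0.724). Of 13 SRF, YAP and actin genes, 6 rose and 2 fell, alike when adjusted over the list alone, without a call for the list (camera adjusted p = 0.215). Those that rose included Ankrd1 (1.90 ± 0.23), Cyr61 (1.32 ± 0.37), Thbs1 (1.07 ± 0.16) and Tagln (1.02 ± 0.31). None of the list fell without FBS replicate 2 or 3, and 1 fell without KSR replicate 2 or 3. Cyr61 was at 0.84 without KSR replicate 1 and did not pass without FBS replicate 2 or 3, nor Tagln without FBS replicate 1 or 2, and without KSR replicate 2 or 3 Tagln was too low to be tested. Of 4 Wnt targets, Tcf7 (-0.29 ± 0.10) fell and none rose (0 adjusted over the list alone), and Tcf7 did not pass when any library but KSR replicate 1 was left out (-0.18 without KSR replicate 3, list adjusted p = 0.318).

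Genes of lipid synthesis were higher in KSR. Of 22 sterol genes tested, 13 rose and none fell (15 and 0 adjusted over the list alone). With 1 library left out, the count that rose ranged from 9 (without KSR replicate 2) to 17 (without FBS replicate 1 or KSR replicate 1). The demethylation enzymes Msmo1 and Cyp51 rose by 1.66 ± 0.27 (30.7 to 95.3 RPKM) and 1.28 ± 0.21 (13.4 to 33.8), and the mevalonate pathway kinase Pmvk by 1.19 ± 0.18. The sterol median was 0.64 (camera adjusted p = 0.000481, adjusted p = 0.594 with an estimated correlation). Of 12 fatty acid synthesis genes, 8 rose and none fell, alike when adjusted over the list alone, with 5 rising without FBS replicate 3. The desaturases Fads2 and Fads1 rose by 1.60 ± 0.16 (25.8 to 79.1 RPKM) and 1.43 ± 0.11 (26.4 to 72.4), and the malic enzyme Me1 by 0.97 ± 0.12. The fatty acid median was 0.44 (camera adjusted p = 0.00122, adjusted p = 0.594 with an estimated correlation). Of 9 PPAR targets, 6 rose and 2 fell (6 and 3 adjusted over the list alone), with Angptl4 (1.39 ± 0.15) and the carnitine transferase Cpt1a (0.91 ± 0.09) higher and the fatty acid binding protein Fabp3 (-1.19 ± 0.10) lower. That list was not called (adjusted p = 0.215) except with no filter on low values, and 1 of its genes fell without FBS replicate 1, 2 or 3.

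Genes of glycolysis and the hypoxia response were lower in KSR. Of 17 tested, 11 fell, 1 rose and 5 did not pass, alike when adjusted over the list alone. The stress-induced gene Ndrg1 fell by 1.93 ± 0.15 (94.0 to 24.3 RPKM), the mitophagy receptor Bnip3 by 1.37 ± 0.35 (76.2 to 32.9), the kinase Pdk1 by 1.28 ± 0.35, not past the test without FBS replicate 1, and Ankrd37 by 1.21 ± 0.30. The median was -0.72 (camera adjusted p = 0.00661, adjusted p = 0.594 with an estimated correlation). KSR replicate 3 stood nearest to FBS for these genes, with 58.1 RPKM of Bnip3 against 22.6 and 18 in KSR replicates 1 and 2, and without it 2 genes rose. Of 13 genes of the unfolded protein and amino acid response, 8 rose, 1 fell and 4 did not pass, alike when adjusted over the list alone. The glutathione-degrading enzyme Chac1 rose by 2.01 ± 0.34 (3.94 to 17.7 RPKM), the pseudokinase Trib3 by 1.94 ± 0.47, the transcription factor Atf3 by 1.46 ± 0.26 and Herpud1 by 1.23 ± 0.17. The member that fell was Hspa5 (-0.45 ± 0.11), the main chaperone of the endoplasmic reticulum. The median was 0.87 (camera adjusted p = 0.0158, adjusted p = 0.594 with an estimated correlation). Of 9 oxidative stress genes, Nqo1 (1.32 ± 0.13) and Gsr (0.82 ± 0.11) rose and Prdx1 (-0.43 ± 0.13) fell, alike when adjusted over the list alone, and the list was not called (adjusted p = 0.72). Prdx1 did not pass without FBS replicate 1 or 2.

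Genes of differentiated trophoblast were then compared. Of 9 syncytiotrophoblast genes, 5 fell, 1 rose and 3 did not pass (6 and 1 adjusted over the list alone). The nuclear receptor Pparg fell by 1.96 ± 0.36 (5.83 to 0.599 RPKM), Ly6e by 1.13 ± 0.18, the repressor Ovol2 by 1.06 ± 0.15 and Cebpa by 1.00 ± 0.13. Their median was -0.67 (camera adjusted p = 0.0162, adjusted p = 0.594 with an estimated correlation) and -1.02 without KSR replicate 1, and with genes of at least 5 RPKM 2 fell and the list was not called. Of 7 trophoblast giant cell genes, Prl2c3 (-3.25 ± 0.90), Prl2c2 (-3.07 ± 0.79) and Ctsj (-2.77 ± 0.78) fell and Mmp9 (1.23 ± 0.27), a gelatinase, rose, alike when adjusted over the list alone, and the list was not called (adjusted p = 0.236). FBS replicate 1 stood apart, with 509 RPKM of Prl2c3 against 33.3 and 54.1 in the other FBS libraries and 4.37 to 17.2 in KSR. Prl7a1 (-4.02 ± 0.73) and Prl2c5 (-3.43 ± 0.75) fell too, with 76.5 RPKM of Prl7a1 in FBS replicate 1 against 5.48 and 15.9. Prl2c genes are near-identical copies whose reads the counting may have split, so that their separate values are uncertain. Without FBS replicate 1 the changes of Prl2c3, Prl2c2 and Ctsj were -2.07, -2.01 and -1.79. Without KSR replicate 2, or with limma-voom on recovered reads, none of the 3 giant cell genes passed, and Prl7a1 and Prl2c5 did not pass with voom, while without FBS replicate 2 the list was called, with 5 genes falling. Of 5 spongiotrophoblast and glycogen cell genes, Nrk (-1.71 ± 0.46) and the connexin Gjb3 (-0.67 ± 0.10) fell and the VEGF receptor Flt1 (0.76 ± 0.18) rose (3 fell and 1 rose adjusted over the list alone), and the list was not called (adjusted p = 0.268). Nrk, at 113 RPKM in FBS replicate 1 against 28.0 and 44.3, did not pass without KSR replicate 2 or 3, and 4 members fell without FBS replicate 2.

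Further lists served to describe growth state and other cell types. Of 13 imprinted genes, 7 rose and 5 fell, alike when adjusted over the list alone, with Dlk1 (2.07 ± 0.34), Mest (1.72 ± 0.19) and the noncoding Meg3 (1.51 ± 0.09) higher and the placental growth restrictor Phlda2 (148.4 to 37.2 RPKM) lower, and the list was not called (adjusted p = 0.605). Of 20 cell cycle genes, 5 fell and 1 rose, alike when adjusted over the list alone, with the replication helicase subunits Mcm2 (-0.57 ± 0.07) and Mcm7 (-0.41 ± 0.07) and the cyclin Ccnb1 (-0.42 ± 0.12) lower and 14 genes not past the test (list adjusted p = 0.132). The helicase subunit that rose was Mcm5 (0.33 ± 0.09), a gene of chromosome 8 whose change was -0.12 after centring by chromosome and did not pass without FBS replicate 3 or KSR replicate 2. Of the cell cycle genes 3 fell without FBS replicate 2, while 2 rose and 4 fell without KSR replicate 1. Ccnb1 did not pass without FBS replicate 2 or KSR replicate 2, and the list was called as lower without FBS replicate 3 or KSR replicate 3. Of 12 CDK inhibitors and p53 targets, 4 rose and 5 fell (4 and 6 adjusted over the list alone), with the inhibitors Cdkn2a (0.92 ± 0.09) and Cdkn2b (0.83 ± 0.13) higher (list adjusted p = 0.72). The largest change was the fall of the inhibitor Cdkn1c (-1.04 ± 0.30), which did not pass without FBS replicate 1 or 3 or KSR replicate 2 or 3. Of 7 pluripotent stem cell markers, Utf1 (-1.68 ± 0.14) and Dppa5a (-0.89 ± 0.24) fell and Klf2 (1.16 ± 0.31) rose, alike when adjusted over the list alone (list adjusted p = 0.357). Klf2 and Dppa5a did not pass without FBS replicate 2, nor Klf2, a gene of chromosome 8, after centring by chromosome, nor Dppa5a without KSR replicate 2, and without FBS replicate 3 it was too low to be tested. Of 3 primitive endoderm markers tested, the endocytic adaptor Dab2 rose by 2.17 ± 0.27 and Gata4 did not pass, at 4.11 and 3.31 RPKM, alike when adjusted over the list alone (list adjusted p = 0.449). Of 8 interferon response genes, Irf1 (1.31 ± 0.08) rose and Usp18 (-0.92 ± 0.28) fell, alike when adjusted over the list alone (list adjusted p = 0.924), and Usp18 did not pass without FBS replicate 1, FBS replicate 3, KSR replicate 2 or KSR replicate 3. Of the interferon genes 2 fell without FBS replicate 2, 4 fell without KSR replicate 1, and 2 rose without KSR replicate 3. Of the RNA quality list only the histone genes Hist1h2bc (4.85 and 3.35 RPKM) and Hist1h1c (3.20 and 3.46) were tested and neither passed, also when adjusted over the list alone (list adjusted p = 0.72), although 1 of them fell without FBS replicate 2. The list adjusted p-values are from camera in limma with Benjamini-Hochberg adjustment over 26 lists, and with an estimated correlation none of the 26 passed.

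**Figure D3:**
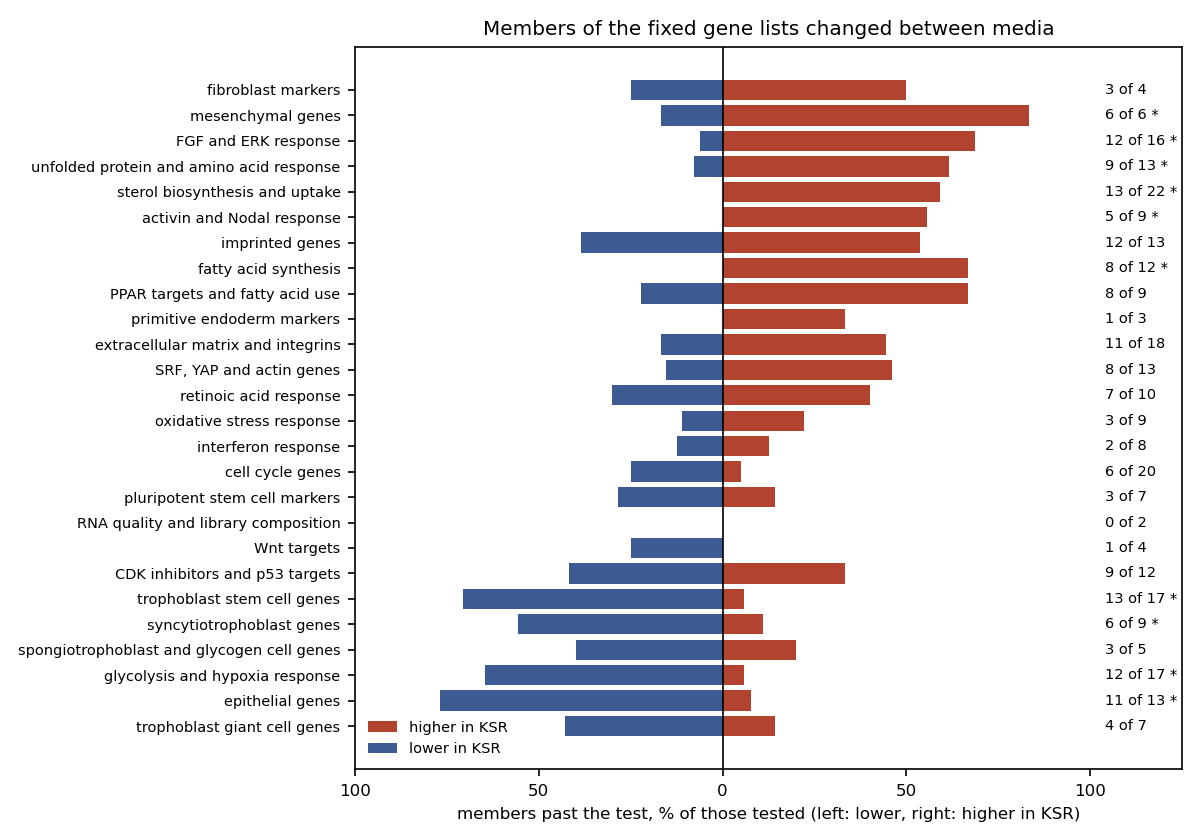
Share of the tested members of each fixed list that were higher (right) or lower (left) in KSR at an adjusted p under 0.05, with the number past the test of those tested at the right and an asterisk for the 10 lists called by camera. Epithelial genes (11 of 13) stand mostly to the left and sterol genes (13 of 22) wholly to the right.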

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

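The rows outside the comparison of genes were tested in the same way after the results had been seen. Of 62 rows without a gene symbol that had a mean of at least 1 RPKM, 9 rose and 6 fell in KSR. This is a smaller share than the 42% that changed among the genes tested.

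Of 2105 symbols with at least 2 tested rows, 14 had both a row that rose and a row that fell in KSR (limma with Benjamini-Hochberg adjustment over 14277 rows), which the use of 1 row per symbol leaves out. Jade1, a chromatin and ubiquitin ligase factor, had a row that rose by 1.58 ± 0.11 on the log2 scale (12.3 ± 0.9 to 38.9 ± 5.23 RPKM, SD, n = 3) and another at -1.27 ± 0.35 (6.01 ± 4.04 to 1.62 ± 0.186). For the vesicle protein Tpd52 the changes were 0.97 ± 0.15 and -1.37 ± 0.17, and for Arhgef25 0.84 ± 0.14 and -1.17 ± 0.17. Esrrb had 1 row that rose by 2.02 ± 0.21 and 1 at -0.62 ± 0.17, so that the lesser row reached 27.7 RPKM in KSR against 22.0 for the other. These genes were chosen after their values were seen, and which transcripts the rows stand for was not analysed here.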

How the results depend on the processing

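Of the settings below, limma-voom, the sum of repeated rows, centring by chromosome and the GC and length correction were chosen after the data were seen, and the predictions for the other splits were written after their results were seen. Over all settings 3405 to 5327 genes changed, and the 3372 to 4593 genes that each shared with the 4603 all kept their direction. Leaving out 1 library gave 3522 to 4313 changed genes (1935 to 2253 higher, 1585 to 2060 lower), 762 to 825 of at least 2-fold and 9 to 11 lists called. Changes of at least 2-fold numbered 802 in the main test and ranged from 439 with a mean of at least 5 RPKM, where fewer genes are tested, to 1188 with a pseudocount of 0.1, with 1187 in voom and 989 with a pseudocount of 0.5. With an estimated correlation 0 of the 10 lists stayed called, at correlations of 0.057 to 0.7, estimated from few libraries. Over the alternatives in which they were high enough to be tested, named genes kept direction and call in 2447 tests, lost the call in 50, gained it in 1 and turned in 5. Median log2 fold changes or tests that turned direction were, with at least 5 RPKM, interferon 0.148, retinoic acid -0.479 and SRF, YAP and actin -0.017; with quantile normalization, interferon -0.012; with GC and length correction, interferon 0.053; and centred by chromosome, CDK inhibitors and p53 targets -0.26 and Mcm5 -0.12. Esrrb turned to 0.29 with the mean of its rows, 0.30 with their sum and 0.28 with voom, as its rows moved apart. Without a library, interferon ranged from -0.376 to 0.136 and turned without FBS replicate 3, KSR replicate 2 or KSR replicate 3, the RNA quality list from -0.271 to -0.009 (turned by its test without FBS replicate 3), and Hist1h1c from -0.027 (without FBS replicate 1) to 0.379. None of the lists that turned was called, and apart from fewer genes and the split of Esrrb the cause was not tested. A block by summed passage number gave 3834 changed genes, but libraries with the same sum did not deviate together (r = -0.109, -0.226 and -0.194 across genes), so the numbers were not taken as pairs. The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split alone gave as many genes (1 of 10, 4603 against 0 for the highest other), as many 2-fold genes (1 of 10, 802 against 0) and as many lists (1 of 10, 10 against 8). The other splits had 39 to 236 genes at an unadjusted p under 0.05 in limma, and 3 to 8 lists called by camera.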

Other observations

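The lists and tests of this part were chosen after the results were seen, except that the tests by GC content and length and by the spread on chromosome 8, though chosen after the data, were set before their own values were seen. Several genes of the LIN28, HMGA2 and IGF2BP axis, tied to growth of early lineages, moved apart between the media. Igf2bp2 fell by 4.79 ± 0.10 on the log2 scale and its relative Igf2bp3 rose by 2.39 ± 0.12 (3.8 to 24.0 RPKM), while Igf2bp1 fell by 0.25 ± 0.06 but did not pass without FBS replicate 2. Hmga2 fell by 2.74 ± 0.13 and Lin28a by 1.18 ± 0.12. Their growth factor Igf2 did not pass the test, at 438 and 528 RPKM, but of its binding proteins Igfbp2 (15.6 to 103 RPKM) and Igfbp4 (10.6 to 91.5) rose and Igfbp3 fell (4.52 to 0.578). Of 11 genes tested, 4 rose and 5 fell.

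Of 12 tested genes of germ cells and the piRNA pathway, 5 fell and 2 rose in KSR. The tudor protein Rnf17 fell by 2.19 ± 0.12 (30.7 to 5.95 RPKM), Gtsf1l by 2.67 ± 0.19, the helicase Ddx4 by 0.85 ± 0.14 and Piwil2 by 0.72 ± 0.13, whereas Tex15, a gene of chromosome 8, rose by 1.94 ± 0.10 (2.23 to 11.4). Of 8 tested genes of prostaglandin synthesis and signalling, 2 rose and 1 fell, with a median of -0.03. Those that rose were both inducible enzymes of prostaglandin E2 synthesis, Ptgs2 by 2.43 ± 0.15 (0.0958 to 4.94 RPKM) and Ptges by 2.84 ± 0.14, and the degrading enzyme Hpgd fell by 1.39 ± 0.38, but not past the test without KSR replicate 2 or 3.

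Genes of some chromosomes were shifted together: 85% of the 618 tested genes of chromosome 8 were higher in KSR (median log2 fold change 0.45) and 81.8% of the 264 of chromosome 18 (0.35), while 26.8% of the 504 of chromosome 6 were (-0.28), each in all 3 libraries against all 3, with an adjusted p of 0.0005 in 10000 permutations of genes over 20 chromosomes, from the smallest p they can give. Chromosome 1 had the same adjusted p (median 0.19), and in all 11 of 20 chromosomes passed 0.05, some of them only 0.04 from all genes, so these 3 were singled out by the size of their shift. The permutations set each chromosome's median against the median of all chromosome medians and took genes as independent. Their p therefore does not measure the spread between libraries. The values argue against GC content and length, since chromosome 8 stood 0.45 ± 0.023 above all genes after their correction, and against a segment or a few genes of chromosome 8, since the lowest of 4 equal runs of its genes in map order stood at 0.41 ± 0.042. For chromosome 18 a segment and the whole cannot be told apart, as its lowest run (0.2 ± 0.077) lies within its error of the bound set. On chromosome 6 the values argue against a common shift of all of it, since the highest run stood 0.29 ± 0.056 above the next, with medians of -0.38 to -0.32 in the other 3. Whether that run was itself lower than all genes (-0.04 ± 0.033) stays open, as it lies between the bounds. On chromosome 1 the medians of the 4 runs were 0.03, -0.03, 0.45 and 0.54. The spread of fold changes on chromosome 8 was 0.95 ± 0.058 times that of other genes, within the bounds set for a common step. Any cause that shifts its genes alike would give the same, so this does not single out a difference in copies. Such a difference for chromosome 8 in part or all of the cells is a candidate explanation that was not tested, with no DNA measured here. An effect of the medium itself was not tested, since every KSR library also had another passage history than the FBS libraries.

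The epithelial and mesenchymal changes may come from cells of another type, but in KSR the highest of the abundant fibroblast transcripts Col1a2, Col3a1, Postn and Lox was 0.073 RPKM, beside 15.2 for Col1a1, which argues against fibroblasts. Chromosome shifts do not account for them, as 17 of the 17 changed members of both lists were called in the same direction after centring by chromosome. A change of state of the cells in KSR, from medium, dish coating or passage, stays open as a hypothesis that the design does not divide.

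The tables argue against reads placed on the wrong Prl2c copy as the source of the lower giant cell genes, since this leaves the sum over the copies as it is and the highest KSR library had 0.45 times the share of Prl2c reads of the lowest FBS library. Whether shared reads were dropped is not known and stays open. Prl2c2, Prl2c3 and Ctsj, the members that fell, had a median log2 fold change of -2.01 without FBS replicate 1 (largest SE 0.47). All still passed, so their falls in these libraries did not rest on FBS replicate 1 alone. They were picked for passing the main test, which favours genes also higher in the other FBS libraries, so they cannot answer for the list. For Prl3d3, Prl3b1 and Prl2a1, which did not pass in the main test, the median without FBS replicate 1 was -0.54 (largest SE 0.42). Prl2a1 stood at 0.37 ± 0.32. These values met the bound set for FBS replicate 1 alone but cannot decide it. Without it the means of Prl3d3 and Prl3b1 were too low to be tested, where the log2(RPKM + 1) scale understates changes. Both passed without FBS replicate 2 (limma adjusted p = 0.00964 and 0.0261). The calls of Prl2c2, Prl2c3 and Ctsj ended without KSR replicate 2 and with voom. The changes of Prl2c2, Prl2c3 and Ctsj were -3.07 ± 0.79, -3.25 ± 0.90 and -2.77 ± 0.78 in the main test, -2.70 ± 0.90, -2.78 ± 1.01 and -2.41 ± 0.89 without KSR replicate 2 and -3.63 ± 1.54, -3.45 ± 1.37 and -3.15 ± 1.35 with voom, so that the SE grew. A larger share of differentiating cells in FBS was not tested and stays open.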
